A study of Mus musculus with 2 samples.

How the data were processed

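Neural precursor cells from the forebrain of mouse embryos at day 11.5 (Jcl:ICR strain) were infected with a control retrovirus or with a retrovirus carrying HMGN1. Per the labels, the infected cells were replated 3 days after infection and kept for 1 day without FGF2 and EGF, the growth factors that hold precursors in division, before total RNA was taken. The RNA was labelled with biotin by the GeneChip whole-transcript kit, per the labels' protocols, and hybridised to 1-colour arrays. The series has 2 arrays, 1 per virus.

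The deposited table holds 28944 probe set intensity values per array on a linear scale. How the authors corrected background, normalized and summarised the probes into these intensity values is not given in the sources used here. The deposited intensities ran from 3.08 to 18209 on the control virus array and from 3.56 to 18892 on the HMGN1 virus array, with medians of 101 and 98.8, and no further normalization was applied. Pearson's r between the arrays was 0.996 across probe sets on the log2 scale, and probe sets are not independent replicates. The same value stood in both columns for 749 probe sets, 2.59% of the table. Detection calls and probe-level signals were not used here.

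Gene names came from GEO's platform annotation, in which 21789 probe sets had 1 gene symbol, 1621 had several and 5534 were unnamed here. Only probe sets with 1 symbol entered the gene table, and 21698 of them matched the RefSeq gene table of assembly GRCm38.p6 by gene number. That table changed no symbol and supplied RNA classes and gene span, the distance from a gene's annotated start to its end, introns included. The deposited table names no genome build, so no coordinates are given.

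Values were taken as log2(intensity + 16), and a difference is always HMGN1 virus minus control virus on that scale, which understates the change of dim genes. Each of 19938 genes took its value from its brightest probe set by the mean of both arrays. A gene counted as detected when that mean reached the 95th percentile of 1035 olfactory receptor probe sets, a family hardly used in brain precursor cells. This floor corresponded to an intensity of 85.9 and left 11325 genes. Probe sets can also catch near-identical copies of a gene, so values of multi-copy families such as Hmgn2, the histones and the ribosomal proteins are uncertain.

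With 1 array per group there are no residual degrees of freedom, so no test between the groups was run and no p-value is given. Percentiles among random lists and bootstrap intervals compare genes or probe sets within these 2 arrays. Differences describe these 2 arrays and have no replicate check. Genes were counted by a fixed size, 1.5-fold. As a measure of scatter between probe sets on this pair of arrays, the log2 differences of different probe sets of 1 gene had an SD of 0.0891 over 683 genes, and those of all detected genes an SD of 0.111. The SD between probe sets leaves out variation shared by a whole array, RNA preparation or culture. At low signal the scatter was larger: the differences of 1027 olfactory receptor genes had an SD of 0.156 and a median of -0.050. The number of arrays limits the precision.

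Before the data were examined, 26 gene lists were fixed for cell types, signalling pathways, stress responses and cell types that the culture could also hold. A list's median difference was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins. A list was said to stand apart under the 2.5 or over the 97.5 percentile. About 1.05 of the 21 lists with at least 5 detected members would do so by chance if genes varied independently. Genes of a list may vary together between any 2 cultures, and some lists share members, so this number may be too low. The named genes followed a rule fixed at the same time. It takes Hmgn1 and its family, the 10 highest and 10 lowest detected genes (leaving out predicted, microRNA and small nucleolar RNA genes), 12 genes fixed by name, of which 11 were analysed here, and the 2 highest and 2 lowest detected members of each list described. Any other gene named was chosen after its value was seen.

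The alternatives fixed beforehand were quantile normalization, centring, removal of the intensity trend by loess over a span of 0.3, other floors, the mean of a gene's probe sets, probe sets of several genes, a 2-fold size, offsets of 1 and 64, list means and unmatched random lists. Added after seeing the data were a smaller size of 1.25-fold (a log2 difference of 0.32), counts without small RNA genes, offsets for lists and named genes, removal of the trend with gene span, and random lists matched on mean expression in 5 bins and gene span in 10. A gene span was known for 11297 of the 11325 detected genes.

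The code was tested on simulated data made from these arrays, with 200 genes changed among 11093 detected genes and a noise SD of 0.111. The 1.5-fold size took in all 50 genes changed 2-fold, 26 of 50 changed 1.5-fold, 1 of 50 changed 1.25-fold and 0 of 10893 unchanged genes. Of 100 lists of 16 unchanged genes, 3 stood apart, and of 20 lists raised by 0.1 on the log2 scale, 15 did. The simulated noise was independent between probe sets and had no trend with gene span. These rates therefore need not hold for lists of genes that vary together. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.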

Results

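Whole-transcript arrays measured RNA levels in embryonic mouse forebrain precursor cells that had received a control retrovirus or an HMGN1 retrovirus and had then spent 1 day without mitogens. HMGN1 is a chromatin protein that binds nucleosomes. The 2 arrays, 1 per virus, give a single comparison, which asks how extra HMGN1 alters gene expression when precursor cells begin to differentiate. Differences are given on the log2 scale as HMGN1 virus minus control virus, without replicates, and describe these 2 RNA samples.

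Hmgn1 itself was higher in the HMGN1 virus sample. Its intensity was 230 with the control virus and 348 with the HMGN1 virus, a log2 difference of 0.57 or 1.48-fold on the scale with an offset of 16, and 1.52-fold without an offset. It was among the 3 highest of 11325 detected genes. The other members of this nucleosome-binding family stayed close to their control values. Hmgn2 differed by 0.13 on its brightest probe set and by -0.049 to 0.073 on its 4 other probe sets, Hmgn3 by 0.040 and Hmgn5 by -0.032. The spread between probe sets of 1 gene was 0.0891 (SD), so only the Hmgn1 difference was several times that size. Whether the Hmgn1 probes lie in the part of the transcript carried by the virus is not known from the sources used here.

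The 3 highest genes were Gfap, the intermediate filament of astrocytes, at 406 and 615 (0.58, 1.49-fold), Ccdc25 at 107 and 166 (0.57) and Hmgn1, in an order that depends on the offset (with an offset of 1, Ccdc25 comes first and Gfap after Hmgn1). They were followed by Zfp804a (0.48), Elovl7, a fatty acid elongase (0.48), Enpp6, a choline phosphodiesterase of newly formed oligodendrocytes (0.46), Ppp4r2 (0.44), the membrane skeleton gene Epb41l2 (0.42), Cfap54 (0.41) and Llph (0.41). A second, dimmer probe set of Cfap54 gave 0.12, and those of Llph gave 0.077 and 0.46. The 10 lowest genes under the naming rule included 4 short noncoding RNAs. They were the Y RNA Rny1 (1001 and 573, -0.79), the 5S ribosomal RNA copy n-R5s136 (-0.61), the vault RNA Vaultrc5 (-0.55) and the minor spliceosome RNA Rnu12 (-0.53). The others were Tmem38b (-0.46), the olfactory receptor Olfr154 (-0.41), A3galt2 (-0.41), the histone pseudogene H2bu1-ps (-0.40), the histone gene H2bc22 (-0.39) and the G protein subunit Gng5 (-0.39). The second probe set of Tmem38b went the other way, at 0.37.

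No detected gene was at least 1.5-fold higher and 8 were at least 1.5-fold lower. All 8 were short noncoding RNAs, namely Snord47, Rny1, Snord118, Snord73b, Snord33, Snora31, n-R5s136 and Snord53, so no protein-coding gene passed this size. Gfap, Hmgn1 and Ccdc25 passed it when an offset of 1 replaced 16. With a log2 difference of 0.32 as the size, chosen after seeing the data, 56 genes were higher and 59 lower, and without small RNA genes 55 were higher and 30 lower. This split depended on the scaling: centring on the median of detected genes, a shift of 0.027, gave 29 higher and 82 lower, and removing the intensity trend gave 37 and 70. An offset of 64 gave 10 and 29. At any size, 4075 of 10882 detected protein-coding genes were lower and most were higher. Counts of list members higher or lower are to be read beside this share.

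**Figure D1:**
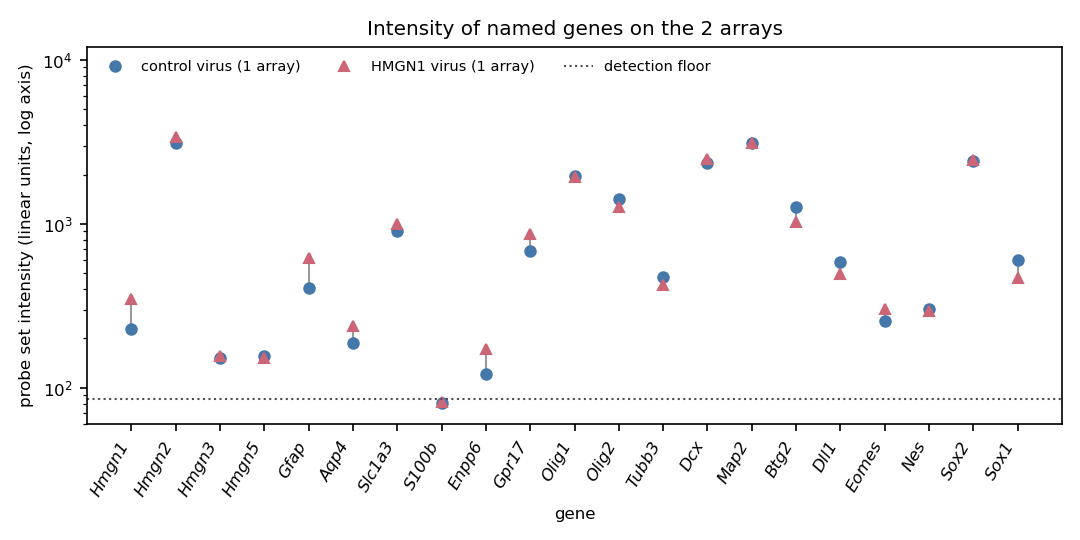
Probe set intensity (linear units on a log axis) of named genes on the control virus array (circles) and the HMGN1 virus array (triangles), 1 array each, with the detection floor at 85.9 as a dotted line. Hmgn1, Gfap, Aqp4, Enpp6 and Gpr17 are higher with the HMGN1 virus, while Btg2, Dll1 and Sox1 are lower and S100b lies under the floor.

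Genes of the oligodendrocyte lineage were higher in the HMGN1 virus sample. Of 20 listed genes, 16 were detected, 11 were higher and 4 lower, and their median difference was 0.13, at the 99.99 percentile of matched random lists, whose middle 95% ran from -0.020 to 0.083. Enpp6 (121 and 172, 0.46) and Gpr17, a receptor of committed oligodendrocyte precursors (686 and 869, 0.33), had the largest differences. Close behind, and named after their values were seen, were Bcas1 (0.32), the tight junction gene Cldn11 (0.32), the myelin regulator Myrf (0.31) and the myelin gene Mbp (0.28). Genes used from earlier stages of the lineage went both ways. The transcription factor Olig2 differed by -0.16, Olig1 by -0.016 and the progenitor proteoglycan Cspg4 by -0.059, whereas Nkx2-2 differed by 0.17, the progenitor receptor Pdgfra by 0.094 and Sox10 by 0.055. Whether earlier and later members differ from each other was not tested. The list stood apart under each alternative run, with percentiles of 99.95 to 100.

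Of 30 listed astrocyte genes 27 were detected, 17 were higher and 9 lower, and 2 reached a log2 difference of 0.32, namely Gfap and the water channel Aqp4 (187 and 237). Below these, and named after their values were seen, came the gap junction gene Gja1 (0.28), Mlc1 (0.22), Agt (0.19) and the lipid carrier Apoe (0.16). The glutamate transporter Slc1a3 differed by 0.15, the glycolytic enzyme Aldoc by -0.072 and the lipid receptor S1pr1 by -0.11, and S100b was under the detection floor (81.1 and 82.2). The list median was 0.056, at the 90.7 percentile, so the list did not stand apart, whereas its mean of 0.084 lay at the 99.92 percentile. In the BMP list, whose ligands promote astrocyte formation, 13 of 16 detected genes were higher. The list was led by Bmp4 (229 and 302, 0.38) and the receptor Bmpr1a (0.19), with Nog (-0.027) and Id2 (-0.12) at the low end, and its median of 0.049 lay at the 81.8 percentile (98.6 for the mean). The JAK-STAT list, the other main pathway into astrocytes, had a median of 0.027 at the 54.8 percentile, between Cish (0.20) and Jak1 (0.20) at the top and Tyk2 (-0.14) and Socs1 (-0.14) at the bottom.

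Genes of neuronal commitment were lower in the HMGN1 virus sample. Of 16 detected genes 11 were lower and 5 higher, with a median of -0.096, below that of all 10000 matched random lists (percentile 0, middle 95% from -0.014 to 0.084). The antiproliferative gene Btg2 (1267 and 1029, -0.30) and the Notch ligand Dll1 (582 and 494, -0.23) were lowest. Eomes, a transcription factor of intermediate progenitors (0.22), and Tagln3 (0.13) went the other way. Genes of more mature neurons did not follow: the median of 28 detected neuron genes was 0.065, at the 94.5 percentile, with 20 higher and 8 lower. Syt1, a synaptic vesicle calcium sensor (0.27), and Neurod6 (0.24) were highest, Tubb3, the neuronal tubulin (476 and 422, -0.17), and Rbfox3 (-0.15) were lowest, Dcx differed by 0.087 and Map2 by -0.0062. Matching on gene span as well moved the neuron list to the 82.1 percentile and left the commitment list at 0.050. The neuron list passed the upper limit for standing apart under 4 alternatives.

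Neural precursor genes as a group stayed within the range of random lists (24 detected, median 0.0063, percentile 9.07). Sox1 (601 and 467, -0.35) and Prom1 (-0.24) were lowest, and Emx2 (0.16) and Slc1a3 (0.15) highest. The precursor markers Nes (-0.041) and Sox2 (0.013, and -0.012 with the intensity trend removed) were close to their control values. The Notch list had a median of -0.019 at the 2.97 percentile, just inside the limit. It was past the limit under 5 alternatives and further inside with gene span matched (5.22) or its trend removed (12.6). Lfng (-0.28) and Notch3 (-0.25) were lowest and Notch2 (0.16) and Rbpj (0.11) highest. A second, dim probe set of Rbpj gave -0.26. Dorsal forebrain genes had a median of 0.029 (50.7 percentile; Eomes and Tbr1 highest at 0.22 and 0.19, Ttr and Wnt3a lowest at -0.075 and -0.070) and ventral forebrain genes -0.049 (3.93 percentile; Gsx2 and Gsx1 lowest at -0.18 and -0.15, Six3 and Dlx5 highest at 0.077 and 0.046).

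**Figure D2:**
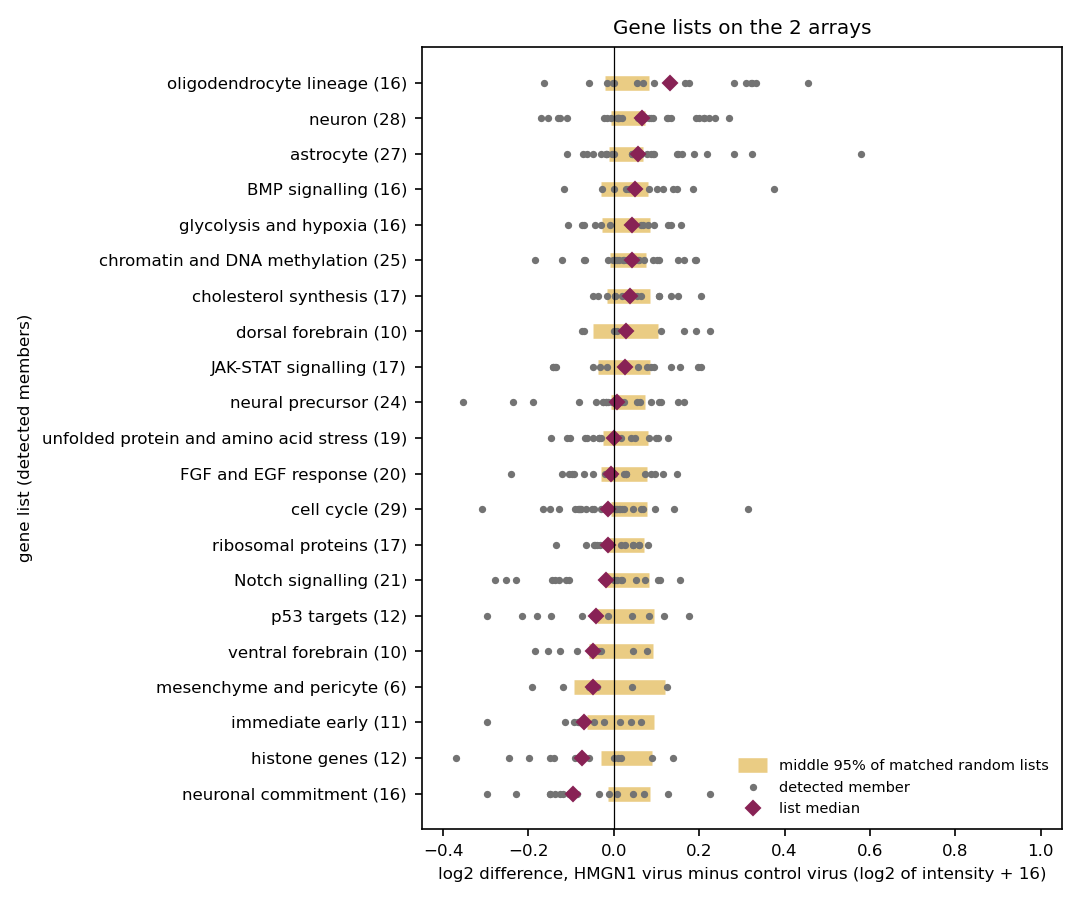
Log2 difference (HMGN1 virus minus control virus, log2 of intensity + 16) of the detected members of 21 gene lists (grey points), each list's median (diamonds) and the middle 95% of medians of matched random lists (bars). The oligodendrocyte lineage median (0.13) lies above its bar and the neuronal commitment median (-0.096) below it.

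A further 4 lists had medians under the 2.5 percentile of lists matched on expression. Cell cycle genes had a median of -0.013 (29 detected, against a middle 95% of random lists from -0.0069 to 0.077), from Ccne2, a cyclin of S-phase entry (-0.31), and the mitotic kinase Plk1 (-0.17) to Kif11 (0.14) and the thymidylate synthase Tyms (0.32). Histone genes had a median of -0.074 (12 detected, 0.060 percentile), with the linker histone H1f10 (811 and 625, -0.37) and H2bc3 (-0.25) lowest and H2bc4 (0.089) and Macroh2a1 (0.14) highest. Immediate early genes had a median of -0.071 (11 detected, 1.39 percentile), with Btg2 and Egr1 (-0.11) lowest and Klf6 (0.041) and Ccn1 (0.064) highest. The p53 targets had a median of -0.043 (12 detected, 2.02 percentile), between Btg2 and Plk2 (-0.21) and Trp53inp1 (0.12) and Ccng1 (0.18). None of these 4 stood apart once random lists were matched on gene span too (percentiles 2.77, 7.52, 11.8 and 3.96). With the gene span trend removed instead, the cell cycle list still stood apart (1.57), and the histone, immediate early and p53 lists did not (28.1, 9.65 and 3.13). The cell cycle list also fell inside the limit after quantile normalization (2.605) and with unmatched random lists (3.96). The p53 list did so with the intensity trend removed (2.86), with the floor at the median of named probe sets (2.74) and with probe sets of several genes (2.545).

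The remaining lists stayed within the range of matched random lists. Their medians were -0.0077 for the FGF and EGF response (11.7 percentile), 0.042 for chromatin and DNA methylation (66.6), 0.039 for cholesterol synthesis (57.5), 0.043 for glycolysis and hypoxia (70.2), 0 for unfolded protein and amino acid stress (14.8) and -0.014 for ribosomal proteins (2.92). The median of 0 fell on Trib3 and Xbp1, which have the same value in both columns. The ribosomal list passed the lower limit with the intensity trend removed (2.025) and without the filter on dim probe sets (1.81), and lay at 45.2 with gene span matched. In the FGF and EGF response, Spry4, a feedback inhibitor of growth factor signalling, differed by -0.24 and the receptor Fgfr2 by 0.15. Markers of other cell types were mostly under the floor: 3 of 15 microglia and macrophage genes were detected (median 0.0080), 1 of 14 endothelial genes (Egfl7, 0.017), 6 of 15 mesenchyme and pericyte genes (median -0.049, 13.1 percentile, but 0.042 without the filter on dim probe sets) and 0 of the 7 erythroid genes analysed. Of 22 interferon response genes analysed, 4 were detected, at Stat2 (0.15), Irf9 (0.061), Psmb9 (0, the same value in both columns) and Bst2 (-0.16). The others lay under the floor, between -0.47 (Oas1a, 75.9 and 50.2) and 0.18 (Mx2), so small differences in them could not be told from scatter.

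Small nucleolar RNAs and a mixed class of other small RNAs were lower in the HMGN1 virus sample, and microRNA genes differed far less. Of 42 detected small nucleolar RNAs, which guide the modification of ribosomal RNA, 39 were lower, with a median of -0.34, led by Snord47 (674 and 360, -0.88). The median was -0.21 with the gene span trend removed. That trend was fitted on small RNA genes too, so its removal may take out part of their own difference. Among 15 other small RNAs 14 were lower (median -0.25), including the RNA components of RNase P (Rpph1, -0.25) and RNase MRP (Rmrp, -0.25), while the 7SK RNA Rn7sk differed by 0.032. Of 84 detected microRNA genes 53 were lower, with a median of -0.043, closer to 0 than the medians of the neuronal commitment, histone and immediate early lists, and 0 were 1.5-fold lower. These classes and RNAs were chosen after their values were seen. Protein-coding genes showed a smaller trend the same way: the median difference was -0.027 in the 1089 genes with the shortest span (0.231 to 4.29 kb) and 0.053 in the 1089 with the longest, and Spearman's rho between span and difference was 0.23 across 10882 genes, which are not independent replicates. Lists of short genes, the histone and immediate early genes among them, lie at the low end of this trend.

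**Figure D3:**
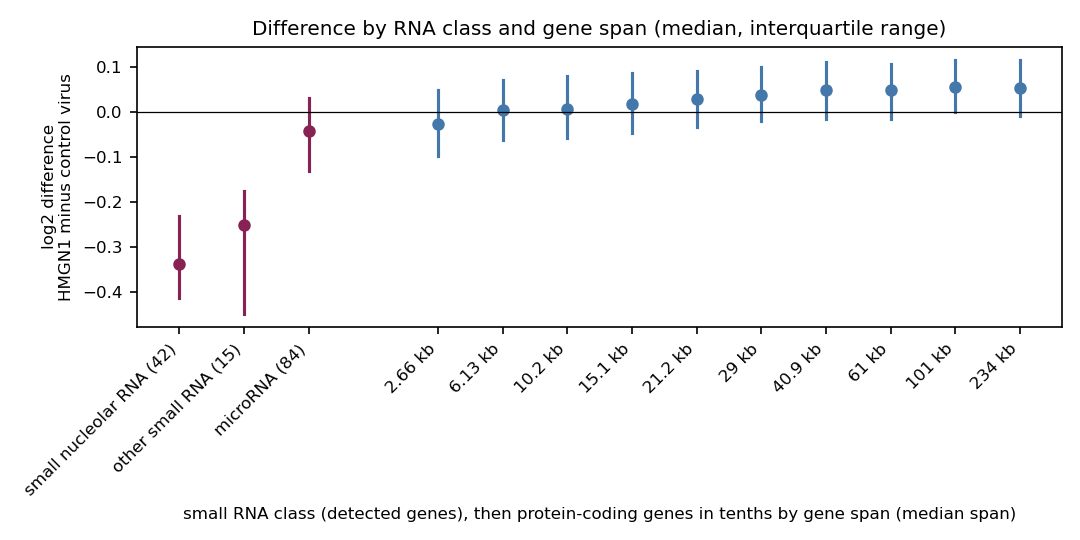
Median and interquartile range of the log2 difference (HMGN1 virus minus control virus) for 3 classes of small RNA genes and for detected protein-coding genes in 10 groups by gene span (median span in kb under each). Small nucleolar RNAs (median -0.34) and other small RNAs (-0.25) lie lowest, microRNA genes lie at -0.043, and the protein-coding medians go from -0.027 at the shortest span to 0.053 at the longest.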

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

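Probe sets outside the gene table held 1 signal higher than in the control: among 2260 unnamed probe sets above the detection floor, 1 was at least 1.5-fold higher in the HMGN1 virus sample (10605429, intensities 166 and 282, log2 difference 0.72), more than any named gene. A further 25 unnamed probe sets were at least 1.5-fold lower, several of them with identical values. Among 1082 probe sets of several genes, 0 were 1.5-fold different either way. The genes of the unnamed probe sets are not known from the tables used here.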

How the results depend on the processing

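The oligodendrocyte lineage and neuronal commitment lists kept their direction under every alternative run, and leaving out a replicate was not possible with 1 array per virus. No paired analysis was possible because each group has 1 array. The count of genes at least 1.5-fold higher, 0, became 3 without a filter on dim probe sets, 3 with an offset of 1 and 56 with a log2 difference of 0.32 as the size. The count lower, 8, became 0 at 2-fold, 59 at that smaller size, 0 without small RNA genes and 4 with the gene span trend removed; these last 3 settings and the matching on gene span were chosen after seeing the data. The neuron list, with a median of 0.065, passed the upper limit for standing apart after quantile normalization (0.065), removal of the intensity trend (0.044), with the floor at the 99th olfactory receptor percentile (0.074) and with probe sets of several genes (0.074), and the astrocyte list passed it by its mean (0.084). For these counts and lists the cause was not tested, apart from the removal of small RNA genes and the change of size, which act by construction. The oligodendrocyte lineage list ran from 0.088 to 0.15 and the neuronal commitment list from -0.13 to -0.059, both past their limit throughout. Over all lists, 21 alternative values passed a limit that the reported value did not and 12 no longer did; centring shifts every gene alike and cannot move a percentile. Of the 21, 5 each were of the Notch and ventral forebrain lists, 4 of the neuron list and 3 of the unfolded protein and amino acid stress list. The 12 were all of the cell cycle, histone, immediate early and p53 lists. Medians of lists that did not stand apart changed sign under at least 1 alternative for the neural precursor, JAK-STAT, chromatin, ribosomal protein and mesenchyme lists. Of the values of named genes, 17 moved by more than the SD between probe sets of 1 gene, Tmem38b most (-0.044 as the mean of its 2 probe sets). The other floors, no filter and probe sets of several genes left the values of named genes as they were. Low signal limits genes near the floor of 85.9, where a difference is compressed by the offset and the scatter is larger (SD 0.156 over 1027 olfactory receptor genes).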

Other observations

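The lists in this part were written after the first results were seen and before their own values were, and the tests of small RNAs, gene span and second lists were chosen only after the patterns they address were seen. A second list of later oligodendrocyte genes, with no member of the first, had 20 detected genes, of which 19 were higher in the HMGN1 virus sample. Its median was 0.13, with the tetraspanin Cd9 (0.23), Gjc3 (0.21), Tns3 (0.21), the lineage transcription factor Zfp488 (0.19) and Sirt2 (0.15) above it and Zfp536 (-0.26) alone below 0. A second list of oligodendrocyte progenitor genes had a median of -0.015 and a mean of 0.033 over 19 detected genes, 9 higher and 10 lower, between Sulf2 (0.25) and Emid1 (-0.14), and lay at the 4.32 percentile of lists matched on expression, inside the limit, and at 1.27 with gene span matched too. The probe set of Mir219a-2, a gene of the oligodendrocyte microRNA miR-219, was at 129 and 173 (0.39), chosen after its value was seen.

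The oligodendrocyte lineage list was higher in the HMGN1 virus sample. Gene span as the whole cause is argued against, because the list lay at the 100 percentile of random lists matched on expression and gene span. Matching on span moved the median of the random lists only from 0.031 to 0.028. A trend with intensity or unequal array distributions was tested only weakly, because the random lists were already matched on mean expression. The percentile was 99.99 as the less extreme of 2 normalizations. A hypothesis is a wider rise of later oligodendrocyte genes, and the second list of later genes lay at the 99.99 percentile in a test that could have failed. The second list was read on the same 2 arrays, and the first was already led by later genes. It therefore extends the pattern to further later genes and is not independent evidence. The second list of progenitor genes, with a median of -0.015, did not share the rise. Whether more cells or more RNA per cell would lie behind such a rise was not tested. Whether HMGN1 or a difference between the 2 cultures, such as their density, the time of plating or the mix of cells, lies behind it stays open with 1 array per virus.

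The neuronal commitment list was lower. Its members have short genes (median span 4.54 kb), so the trend with gene span may contribute: the median of matched random lists fell from 0.035 to -0.00068 when span was matched. The list still lay at the 0.05 percentile there, so the span trend does not account for all of it. It lay at the 0 percentile after quantile normalization and after removal of the trend of the difference with intensity. That is a weak test, because the random lists were already matched on mean expression. GC content, which was not tested, and a difference between the cultures remain open beside HMGN1.

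Small nucleolar RNAs and other small RNAs were lower (medians -0.34 and -0.25), while 84 microRNA genes had a median of -0.043. Lower levels of the genes that host the small nucleolar RNAs are argued against by 20 detected host genes, whose median was 0.033 (95% bootstrap interval -0.033 to 0.082), although Gas5, host of Snord47, was at -0.28. These hosts cover only part of the 42 detected small nucleolar RNAs. Snord118 (-0.78) and Snord33 (-0.67), among the lowest, had no host in this comparison. Lower recovery of short RNAs in 1 of the 2 preparations stays open: 56 probe sets of several genes that include a small RNA had a median of -0.35 (-0.35 over their 14 distinct sets of symbols, 95% bootstrap interval -0.43 to -0.21), but they are mostly of the same RNA types and extend the pattern more than they explain it. The microRNA value goes against an equal loss of all short RNAs, if those probe sets read the short RNA and not its longer precursor transcript, which was not tested. A real fall in small RNAs with HMGN1 would give the same values and stays open too.

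A hypothesis that Gfap and Aqp4 belong to a wider rise of astrocyte genes was tested on a second astrocyte list of 24 detected genes. Its median of 0.031 lay at the 79.12 percentile of lists matched on expression and gene span, under the 90 set beforehand as speaking against the hypothesis, with Slco1c1 (0.16) and Vcam1 (0.14) highest and Sox21 (-0.21) lowest. Of its genes 18 were higher and 5 lower, where the median of all detected genes was 0.027. A modest wider rise stays possible, because only 15 of 20 simulated lists raised by 0.1 stood apart. The mean of the first astrocyte list lay at the 99.92 percentile, but it includes Gfap and Aqp4 themselves. It therefore cannot speak for a rise beyond these 2 genes.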
